A study of Homo sapiens with 4 samples.

How the data were processed

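RNA was measured in 4 samples of the human breast epithelial line MCF10A, each with 1 stable transfection (LacZ, Her2, the H1047R variant of PIK3CA, or Her2 with that variant), on 1 array each. Per the labels' protocols, cells grew untreated in SFIHE medium, RNA was column-purified, and biotin-labelled cDNA was prepared with an Affymetrix whole-transcript kit. The deposited values are log2 expression values per probe set, made by the submitters with RMA in the oligo package, per the submitters' processing notes. RMA subtracts background, normalizes between arrays and summarises probes. Versions of these tools, the probe set definition and any filter are not given in the sources used here. The log base follows from RMA and from the range of the values (-0.77 to 12.35) and is not stated by a header. The values are not centred per gene. Medians over all probe sets were 1.17, 1.16, 1.17 and 1.13 in the order of the groups above. Some abundant transcripts, such as GAPDH and ACTB, read low in these values, so levels of different genes were not compared. The cause of the low readings was not tested. The number of arrays limits the precision.

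The table holds 53617 probe sets. The platform annotation used here gave 1 gene symbol for 23871 of them and several for 1842, and 27904 are unnamed here. Symbols were updated through gene identifiers with the RefSeq table of assembly GRCh38.p14, which changed 90. Its coordinates were not printed because the build of the array annotation is not given in the sources used here. It served for names and for which genes neighbour each other. No gene was named from a probe set with several symbols, except that the probe set for ERBB2 and MIR4728 was reported for the introduced gene. ERBB2 and PIK3CA were left out of all counts and lists.

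Before the data were examined, the comparisons, the gene lists, the naming rule and the alternatives were fixed, except where the text says that a choice came after. A counted gene has a probe set with exactly 1 symbol, the one with the highest mean where a gene has several (608 genes before the filter), is no small RNA, and reaches a log2 value of 5 on at least 1 array. This left 4314 of 20917 genes. The filter is stricter on this scale than assumed when it was fixed, and because it asks for 1 array only, it admits genes that are high on a single array. Random lists under the filter therefore contain such genes too.

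With 1 array per group, no test compares 2 groups. Genes were counted when their log2 values differed by at least 1 (2-fold). The effect of each introduced gene was measured in 2 pairs that share no array, and the genes different the same way in both were set against the number that independent lists would share. Departure from additivity was the log2 value with both genes minus each single value plus LacZ. An additive model without interaction was fitted with limma (lmFit, eBayes, Benjamini-Hochberg adjustment), with 1 residual degree of freedom and 3.02 prior degrees of freedom, and its residual is non-additivity. For the 28 gene lists, the median log2 difference was placed among 10000 random lists of the same size matched on mean value in 20 bins, as a description of these arrays. Lists with at least 5 counted members, 19 in all, were described. In each of the 8 comparisons, 0.475 of 19 lists would fall beyond each bound of 2.5% by chance if the genes of a list varied independently. Genes of a list can vary together, so more lists could fall beyond these bounds by chance.

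Named genes were, for each introduced gene, the 12 highest and 12 lowest mean differences among genes at least 2-fold different the same way in both pairs. For both against LacZ they were the 10 highest and 10 lowest, for each single gene against LacZ the 5 highest and 5 lowest, and for departure from additivity the 8 highest and 8 lowest. Members of described lists were named as examples. Uncharacterised symbols were counted but not named. ERBB2 was named always. COL1A1 and COL1A2, below the filter, and members of lists too small to describe were named after their values were seen.

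Alternatives were no filter, a filter at 7, quantile normalization or cyclic loess (3 iterations) of the counted genes, the mean of all probe sets of a gene, small RNAs kept, a 1.5-fold threshold, an intensity trend in eBayes and an adjusted p under 0.1. A filter at 3 and an exchange of the labels of the single-gene arrays were added after seeing the data. Of 730 differences of at least 2-fold among 253 named genes and list members, 2 turned direction under quantile normalization (CDC6 in mutant PIK3CA against LacZ, SCEL in both against LacZ) and 0 under cyclic loess.

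The additive fit was tested on simulated data of 4314 genes with 200 changed with Her2. With equal spread for all genes it recovered 43 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 3, with 1 false call. With spread varying between genes it recovered 0 of 100 at each size after adjustment, and at an unadjusted p under 0.05 56 and 97. There the rule of a 2-fold difference the same way in both pairs found 25 and 97 of the changed genes and 83 unchanged ones, with 99 genes in opposite directions. The arrays themselves gave 18 opposite genes for Her2 and 22 for mutant PIK3CA. The 83 is therefore no estimate of unchanged genes among those found on the arrays. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.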

Results

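Gene expression was measured in MCF10A cells, a non-tumorigenic human breast epithelial line, carrying 1 of 4 stable transfections. The control carried LacZ, a bacterial enzyme gene without a mammalian signalling role. The other cells carried Her2 (ERBB2, a receptor tyrosine kinase), the H1047R variant of PIK3CA (the catalytic subunit of a lipid kinase downstream of such receptors), or both. Each of the 4 groups was measured on 1 array, so no difference has a replicate check and no SD can be given. The labels give the purpose as finding genes controlled by either gene or by the pair. Values are deposited log2 values, so a difference of 1 is 2-fold, and 4314 genes reached a log2 value of 5 on at least 1 array and were counted. The arrays had similar medians over all 53617 probe sets, from 1.13 to 1.17. Across the counted genes, the array labelled with both genes stood farthest from the LacZ array (Pearson's r = 0.647 across genes), against 0.926 for the array labelled Her2 and 0.872 for the array labelled mutant PIK3CA. The filter shapes these values, because it drops genes low on all arrays and admits genes high on a single one. Over all probe sets r was 0.949 for the array labelled with both, 0.967 for Her2 and 0.968 for mutant PIK3CA. There the gap was smaller, and the order of the single-gene arrays turned. Genes are not independent replicates, and these correlations only describe the arrays.

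The introduced genes were examined first, because they check the labels. The probe set that reads ERBB2 (16833839, annotated to ERBB2 and to MIR4728, a microRNA gene lying inside it) went against them. Its value was 5.96 on the LacZ array, 4.29 on the array labelled Her2, 8.48 on the array labelled mutant PIK3CA and 7.39 on the array labelled with both. Thus it was lower by 1.67 log2 units (a difference of -1.67) on the array labelled Her2 than on the LacZ array, and higher by 2.52 on the array labelled mutant PIK3CA. Neighbours of ERBB2 did not follow this order. On the array labelled mutant PIK3CA, STARD3 differed from the LacZ array by -0.90, PGAP3 by -1.04, MIEN1 by -0.84 and GRB7 by -0.95. No probe set is named PIK3CA in the annotation used here, and its level was not analysed here. Every direction below is therefore given for the array labelled with a group, and the labels, above all those of the single-gene arrays, carry this doubt throughout.

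**Figure D1:**
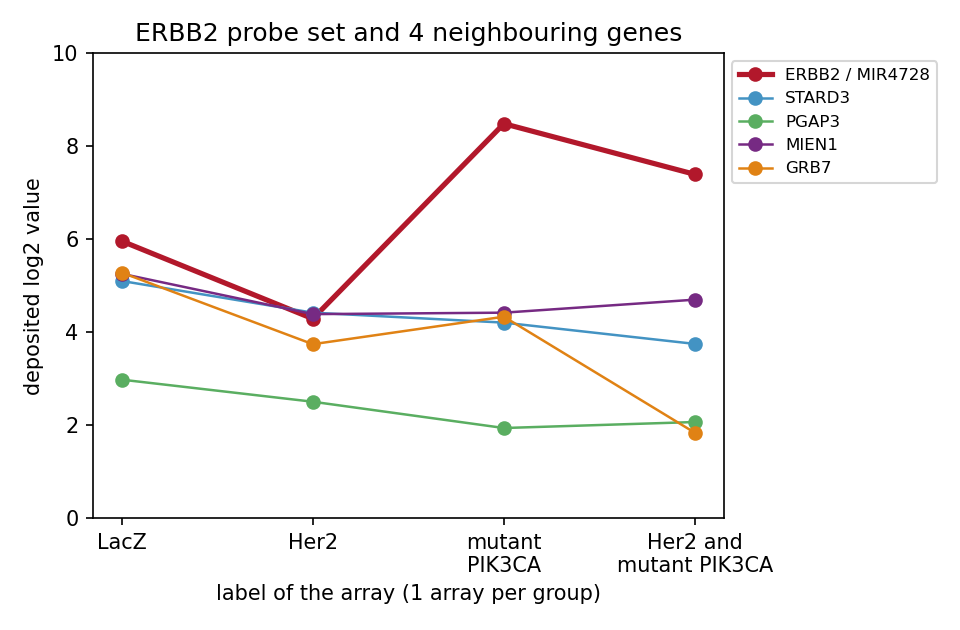
Deposited log2 value (vertical axis) of the ERBB2 probe set and of the neighbouring genes STARD3, PGAP3, MIEN1 and GRB7 on each of the 4 arrays (horizontal axis, 1 array per group, lines only join points of a gene). The ERBB2 probe set reads 8.48 on the array labelled mutant PIK3CA and 4.29 on the array labelled Her2.

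On the array labelled Her2, the mesenchymal list was higher and the epithelial junction list lower than on the LacZ array. The largest differences upwards were in POSTN, the matrix protein periostin, at 5.12, and DPT, the matrix protein dermatopontin, at 4.97. PTX3, a secreted pentraxin, followed at 3.92, HAS2, a hyaluronan synthase at background on the LacZ array (0.98), at 3.03, and ABCA6, a lipid transporter family member, at 2.91. The lowest were the kallikrein protease KLK6 at -2.82, the keratin KRT80 at -2.39, TTC9 at -2.33, the cystatin CST6 at -2.28 and the chemokine CXCL16 at -2.13. Of 11 counted mesenchymal genes, 5 were at least 2-fold higher and 0 at least 2-fold lower, with a list median of 0.90 (0.59 without the filter). FN1 (fibronectin) differed by 2.37, TWIST1, a transcription factor of mesenchymal cells, by 1.83 and LOX, a collagen crosslinking enzyme, by 1.02. The fibroblast markers DPT and FAP were higher on this array too, FAP by 1.57, whereas LUM and DCN differed by -0.14 and -0.16. Of 17 counted epithelial junction genes, 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.68. RAB25, a small GTPase of epithelial trafficking, differed by -1.26, JUP (plakoglobin) by -1.24, the splicing regulator ESRP2 by -1.14 and CLDN7, a claudin, by -1.02. The adherens junction gene CDH1 (E-cadherin) differed by -0.40. Among 10000 random lists matched on mean value, 0 had a median as high as the mesenchymal list and 0 a median as low as the junction list.

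The luminal epithelial list (5 counted genes) had a median of -0.82 on the array labelled Her2, at percentile 0.17 of its random lists, with EHF at -1.29 and KRT7 at -1.23. Without the filter on low values its 21 measured members had a median of -0.01, inside the central 95%. TGF-beta targets had a median of 0.46 (percentile 98.3), with TGFBI at 1.10 and SKIL at 0.71. Mitotic genes had a median of -0.12 and S phase genes of 0.02, and both lay inside the central 95% of random lists. Some mitotic genes lay near background on both the LacZ and the Her2 array, as KIF20A (1.40 and 1.39) and CDK1 (1.66 and 1.42). For such genes a difference near 0 does not show an unchanged level. MAPK output genes, which act downstream of growth factor receptors, had a median of -0.23 at percentile 3.88, with FOSL1 at -1.05 and MYC at -0.80. Without the filter, the 22 measured MAPK genes had a median of -0.22 at percentile 2.08, below the central 95%. In total 239 counted genes differed at least 2-fold, 127 higher and 112 lower. That split turned after cyclic loess normalization, where 42.5% of the genes called were higher, against 53.1% here.

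The effect of the Her2 label was measured a second time between the array labelled with both and the array labelled mutant PIK3CA, which share no array with the first pair. The genes at least 2-fold higher or lower in both pairs are given below with the means of both log2 differences. DPT reached 4.57, HAS2 3.77, PTX3 3.31 and FBN1, the microfibril protein fibrillin, 3.04. IKBIP followed at 2.83, TYMS (thymidylate synthase) at 2.79, LTBP1, a binding protein of latent TGF-beta, at 2.49, ABCA6 at 2.47, PROS1 (protein S) at 2.38, the gelatinase MMP2 at 2.34, MME (neprilysin) at 2.13 and POGLUT3 at 1.90. HAS2 (0.98 and 1.35) and IKBIP (1.00 and 1.54) lay near background without this label, so their values are lower bounds. Lower in both pairs were CALB2 (calretinin) at -3.18, the adhesion receptor ADGRG1 at -2.71, TTC9 at -2.60, KLK7 at -2.50, LSR, a receptor of tricellular junctions, at -2.36 and PRSS8 (prostasin) at -2.33. They were followed by MYO5B, a motor of vesicle recycling, at -2.31, the chloride channel ANO1 at -2.24, the occludin pseudogene OCLNP1 at -2.18, CBLC at -2.16, AP1M2, an adaptor subunit of polarized sorting, at -2.12 and SMOC1 at -2.10. OCLNP1 resembles OCLN in sequence, and its probe set could read both. Some of these means join unequal pairs, as for IKBIP (1.30 in the first and 4.36 in the second), TYMS (1.10 and 4.48) and ADGRG1 (-1.19 and -4.23). For DPT the pairs were closer (4.97 and 4.17).

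In that second pair the junction list was lower as a whole. All 17 counted members were at least 2-fold lower on the array labelled with both than on the array labelled mutant PIK3CA, with a median of -2.17 and CDH1 at -4.06. Mesenchymal genes had a median of 1.23 (0.72 without the filter), with 7 of 11 at least 2-fold higher. Mitotic genes had a median of 2.04 here with 18 of 18 at least 2-fold higher, and S phase genes one of 2.15 with 13 of 13. In the first pair the mitotic median was near 0, but some of these genes lay near background on both arrays there. The amino acid stress response list had a median of -1.49 with 10 of 13 members at least 2-fold lower, against 0.05 in the first pair. Basal epithelial genes (7 counted, median -1.29), ERBB receptors and ligands (6 counted, -1.09), luminal genes (-0.96, and -0.36 without the filter), TGF-beta targets (-0.66, percentile 1.99, and -0.16 inside the central 95% without the filter) and MAPK output genes (-0.61) also lay below the lowest 2.5% of random lists. Cholesterol genes (0.72) and housekeeping genes (0.64) lay above the central 95%.

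This second pair differed at least 2-fold in 815 genes, 432 higher and 383 lower (107 and 136 with the filter at 7). Over both pairs, 104 genes were at least 2-fold different the same way, 52 in each direction (33 higher and 57 lower after quantile normalization), where independent lists would share 12.7 higher and 9.94 lower. Another 18 genes went opposite ways, where independent lists would give 22.5. The correlation of the differences across genes was 0.309.

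On the array labelled mutant PIK3CA, which carries the highest ERBB2 value, genes of mitosis were higher than on the LacZ array. All 18 counted mitotic genes were at least 2-fold higher, with a median of 1.95, and 0 of 10000 random lists reached it. BUB1, a spindle checkpoint kinase, differed by 3.34, HMMR by 3.33, CENPF, a kinetochore protein, by 3.17, CENPE, a kinetochore motor, by 2.79 and the proliferation marker MKI67 by 2.15. S phase genes shared little of this shift, with a median of 0.28 at percentile 43.8 (98.5 without the filter) and 2 of 13 members, CDC6 and RRM2, at least 2-fold higher. The largest single differences were outside the cell cycle. MMP1, the interstitial collagenase, differed by 5.98, CASP14, a caspase of cornified epidermis, by 4.35 (both near background on the LacZ array, at 1.29 and 1.05), SERPINB7 by 4.29, PLD5 by 3.90 and POSTN by 3.83. The lowest were KLK6 at -4.37, DHX40, a putative RNA helicase, at -3.32, EMP3 at -3.32, the interferon-inducible IFITM2 at -3.01 and TMT1A at -2.73.

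Cholesterol synthesis and uptake genes had a median of 0.56 on the array labelled mutant PIK3CA (12 counted, percentile 99.5). STARD4, a cholesterol transport protein, differed by 2.07 and IDI1, an isomerase of the pathway, by 1.16. TGF-beta targets had a median of 0.83 (percentile 99.5), with BHLHE40 at 1.35 and TGFBI at 1.26 but ID1 at -1.08, and a median of 0.08, inside the central 95%, over the 12 members measured without the filter. Junction genes had a median of -0.16, mesenchymal genes of 0.42, basal genes of 0.25, and all lay inside the central 95% of random lists. So did PI3K pathway components (7 counted, -0.17) and FOXO targets (9 counted, -0.28), genes that act in or are repressed by the pathway PIK3CA belongs to. Without the filter, the 16 measured PI3K components had a median of -0.30 at percentile 1.44, below the central 95%. The 21 FOXO targets measured that way had one of -0.10, inside it. Among FOXO targets, BCL6 differed by -1.26 and FBXO32 by -1.15, but GADD45A by 1.68. In total 481 genes differed at least 2-fold, 305 higher and 176 lower. The share of higher genes was 63.4%, against 53.1% after cyclic loess and 49.9% after quantile normalization.

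The effect of the mutant PIK3CA label was measured a second time between the arrays labelled with both and Her2. The mitotic list had a median of 4.39 with 18 of 18 members at least 2-fold higher. Averaged over both pairs, ASPM, a spindle pole protein, differed by 4.32, the mitotic kinesin KIF20A by 4.03, the condensin subunit NCAPG by 3.86, DEPDC1 by 3.84, the topoisomerase TOP2A by 3.83 and CENPF by 3.81. PBK followed at 3.80, KIF14 at 3.80, BUB1 at 3.79, HMMR at 3.73, CENPE at 3.69 and ANLN (anillin) at 3.68. Some of these means join unequal pairs, as for KIF20A (2.28 in the first and 5.79 in the second), while for BUB1 they were closer (3.34 and 4.24). Where the arrays without this label lay near background, as for ASPM (1.13), KIF20A (1.40 and 1.39) and DEPDC1 (1.23 and 1.03), the value is a lower bound and its rank not exact. Lower in both pairs were KLK6 at -3.45, DHX40 at -2.97, EMP3 at -2.77, ABCA6 at -2.38, LSR at -2.36 and HOXB9 at -2.36. HSD11B2, the enzyme that inactivates cortisol, differed by -2.25, the epithelial sodium channel subunits SCNN1B and SCNN1G by -2.16 and -2.09, ADGRF1 by -2.02, the potassium channel KCNK5 by -2.01 and UIMC1, a DNA damage response protein, by -1.95.

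Between the arrays labelled with both and Her2, S phase genes had a median of 2.55 with 13 of 13 at least 2-fold higher, and cholesterol genes one of 1.25 with 8 of 12. Fatty acid synthesis (8 counted, 0.59, and 0.33 inside the central 95% without the filter), glycolysis (7 counted, 0.52, and 0.29) and housekeeping genes (0.52) lay above the central 95% of random lists. Junction genes had a median of -1.30 with 13 of 17 at least 2-fold lower. Amino acid stress genes (-0.88), matrix proteases and their inhibitors (8 counted, -0.87, and -0.51 without the filter), ERBB receptors and ligands (-0.69, and -0.45), basal genes (-0.58) and MAPK output genes (-0.39) lay below it. The mesenchymal median was 0.04. This pair differed at least 2-fold in 657 genes, 394 higher and 263 lower, and the share of higher genes was 60.0%, against 49.1% after quantile normalization, and turned to 97 higher and 113 lower genes with the filter at 7. Over both pairs, 163 genes differed the same way, 113 higher and 50 lower (71 and 76 after quantile normalization), where independent lists would share 27.9 and 10.7. Another 22 genes went opposite ways, where independent lists would give 34.7, and the correlation across genes was 0.400.

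The array labelled with both genes differed most from the LacZ array. Proliferation genes were far higher: ASPM differed by 5.94, KIF20A by 5.78, NCAPG by 5.77, FAM111B by 5.50, DLGAP5 by 5.36, CENPF by 5.32, TYMS by 5.31, CEP55 by 5.30 and DEPDC1 by 5.12. On the LacZ array several of them lay at background (ASPM 1.13, FAM111B 0.90, DLGAP5 0.80, against an array median of 1.17), so these values are lower bounds and their order is not exact. The mitotic list had a median of 4.52 and the S phase list of 2.65, with all 18 and all 13 counted members at least 2-fold higher. Among S phase genes, CLSPN differed by 4.36, CCNE2 (cyclin E2) by 4.29 and the helicase subunit MCM6 by 2.65. The mitotic median exceeded all 10000 random lists. The S phase median lay at percentile 96.7, because random lists matched to it also hold genes that pass the filter on this array alone. Without the filter, 19 of 20 measured S phase genes were at least 2-fold higher, with a median of 2.20 above all 10000 random lists.

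Epithelial genes were lower on the array labelled with both. KLK6 differed by -5.36, LSR by -4.72, ADGRG1 by -4.66, CDH1 by -4.27, HSD11B2 by -4.09, PRSS8 by -4.03, AP1M2 by -3.89, SCNN1B by -3.78, HOXB9 by -3.68 and SPINT1, an inhibitor of membrane serine proteases, by -3.63. The junction list had a median of -2.22 with 15 of 17 members at least 2-fold lower, below all 10000 random lists. JUP differed by -3.29, CLDN7 by -3.26, CDH3 (P-cadherin) by -3.24 and EPCAM by -2.22, whereas the desmosomal genes DSG2 and DSC3 differed by -0.40 and -0.35. Luminal genes had a median of -1.04 (-0.12 inside the central 95% without the filter) and basal genes of -0.77. Among basal genes, the laminin chain LAMB3 differed by -1.67 and KRT16 by -1.52, KRT5 by -0.13, and DST by 2.05.

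Mesenchymal genes were higher, with a median of 1.31 and 8 of 11 counted members at least 2-fold higher, above all 10000 random lists. POSTN differed by 4.55, CDH2 (N-cadherin) by 4.37, the receptor kinase AXL by 2.01, FN1 by 1.78 and TWIST1 by 1.21, and without the filter the median of 21 measured members was 0.71. Of the fibroblast markers, LUM (lumican) differed by 5.48, DPT by 4.45 and DCN (decorin) by 4.32, while COL1A1 and COL1A2, the type I collagen chains, differed by -0.46 and -0.03.

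Cholesterol and amino acid stress lists also differed. Cholesterol genes had a median of 1.29 with 8 of 12 at least 2-fold higher and 0 lower, above all random lists. HMGCS1, an early enzyme of the pathway, differed by 3.36, STARD4 by 2.56 and INSIG1 by 2.54. Amino acid stress genes had a median of -0.63 (percentile 0.55) with 6 of 13 at least 2-fold lower, among them the linked transporter subunits SLC7A5 at -2.81 and SLC3A2 at -2.01, TRIB3 at -1.71 and CHAC1 at -1.59. ERBB receptors and ligands had a median of -0.80 (percentile 1.53), with the ligand HBEGF at -2.43 and EGFR at -0.94, and one of -0.25 at percentile 11.2, inside the central 95%, without the filter. MAPK output genes had a median of -0.57 (percentile 1.06, and -0.37 without the filter), with the phosphatase DUSP6 at -1.50 and MYC at -1.30. Housekeeping genes, listed as a control, had a median of 0.90 (percentile 99.4), with B2M at 2.31, HPRT1 at 1.53 and GUSB at 1.28 but TBP at -0.31, and one of 0.52 at percentile 96.2 without the filter. Fatty acid synthesis (0.43), glycolysis (0.45), hypoxia targets (7 counted, -0.11), p53 targets (9 counted, -0.06), matrix proteases (-0.20), TGF-beta targets (0.09), FOXO targets (-0.41) and PI3K components (0.26) lay inside the central 95%.

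**Figure D2:**
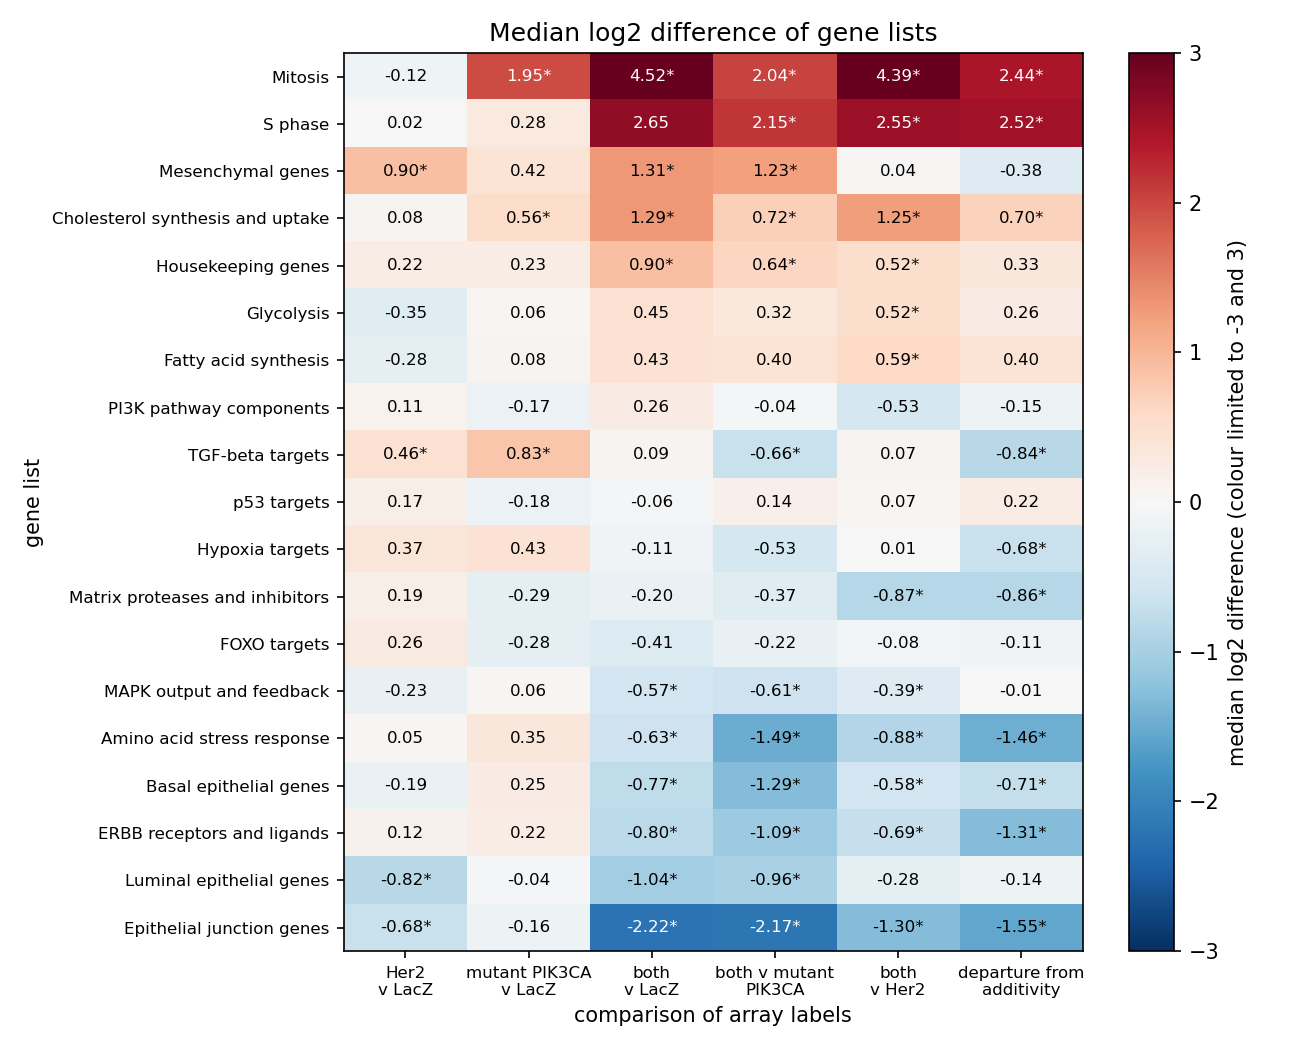
Median log2 difference of each of 19 gene lists (rows) in 5 comparisons of array labels and in the departure from additivity (columns), coloured from blue (lower) to red (higher). An asterisk marks a median outside the central 95% of 10000 random lists matched on mean value; the mitotic list reads 4.52 and the epithelial junction list -2.22 for both against LacZ.

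In total 1075 of the 4314 counted genes (24.9%) differed at least 2-fold between the arrays labelled with both and LacZ, 597 higher and 478 lower, a split that turned to 535 and 573 after quantile normalization. Of these, 160 differed at least 2-fold the same way on the array labelled Her2, 89 of them higher where independent lists would share 17.6, and unchanged groups sharing the LacZ array gave 23 in a simulation. For the array labelled mutant PIK3CA the number was 255, 169 of them higher against 42.2 for independent lists, and 20 in the simulation. That simulation took equal spread for all genes. In the test of the additive fit, unchanged genes at least 2-fold different the same way in both pairs rose from 1 with equal to 83 with varying spread. The 23 and 20 can therefore be too low. The shared LacZ array adds to the overlaps of 160 and 255, which are not a measure of shared effect. A further 716 of the 1075 genes (66.6%) were at least 2-fold different the same way on neither single-gene array. Of these 716, 271 were also at least 2-fold away from additivity, so most leave room for smaller effects of each gene adding up.

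Departure from additivity was taken as the log2 value with both genes, minus each single-gene value, plus the LacZ value. The 8 highest were H2BC14 (a histone H2B gene) at 6.25, H1-5 (a linker histone gene) at 5.99, LUM at 5.88, the interferon-stimulated IFI6 at 4.63, FAM111B at 4.46, DCN at 4.07, the cohesin acetyltransferase ESCO2 at 3.95 and the mitotic kinase CDK1 at 3.91. LUM, DCN, FAM111B and H1-5 read between 0.52 and 1.75 on the other 3 arrays, near background, so their departures and order are not exact. The lowest were MMP1 at -4.81, the growth factor BMP6 at -4.62, SLITRK6 at -4.59, the cadherin CDH11 at -4.47, POSTN at -4.40, the Notch target HES1 at -4.34, the metalloprotease inhibitor TIMP3 at -4.22 and SCEL at -4.02. POSTN was high on each of the 3 arrays with an introduced oncogene (9.19 for Her2, 7.90 for mutant PIK3CA and 8.62 for both, against 4.07), so its departure marks a lack of summation. MMP1 was high only on the array labelled mutant PIK3CA (7.27, against 0.87 to 2.04 on the others).

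The S phase list had a departure of 2.52 with 13 of 13 members at least 2-fold above additivity, the mitotic list one of 2.44 with 15 of 18, and cholesterol genes one of 0.70. Random lists matched to the S phase and mitotic lists had a median departure of 0.48 each, as the filter admits genes high on 1 array. Without the filter the S phase median was 1.97 and the mitotic median 2.44, each above all 10000 random lists. Some mitotic genes lay near background on the LacZ and Her2 arrays, as KIF20A (1.40 and 1.39), so these sizes are not exact. Junction genes lay below additivity, with a median of -1.55 and 12 of 17 members at least 2-fold below. Amino acid stress genes (-1.46), ERBB receptors and ligands (-1.31, and -0.67 without the filter), matrix proteases (-0.86, and -0.50), TGF-beta targets (-0.84, and -0.53), basal genes (-0.71) and hypoxia targets (-0.68) lay below the central 95% of random lists. The hypoxia value vanished without the filter, at 0.00372. In total 800 genes were at least 2-fold away from additivity, 410 above and 390 below, a split that turned to 96 and 149 with the filter at 7. The measure holds the noise of all 4 arrays, and its typical spread over genes corresponds to 0.339 log2 units per array. That value also contains real non-additive effects, and the noise of single genes can be larger.

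**Figure D3:**
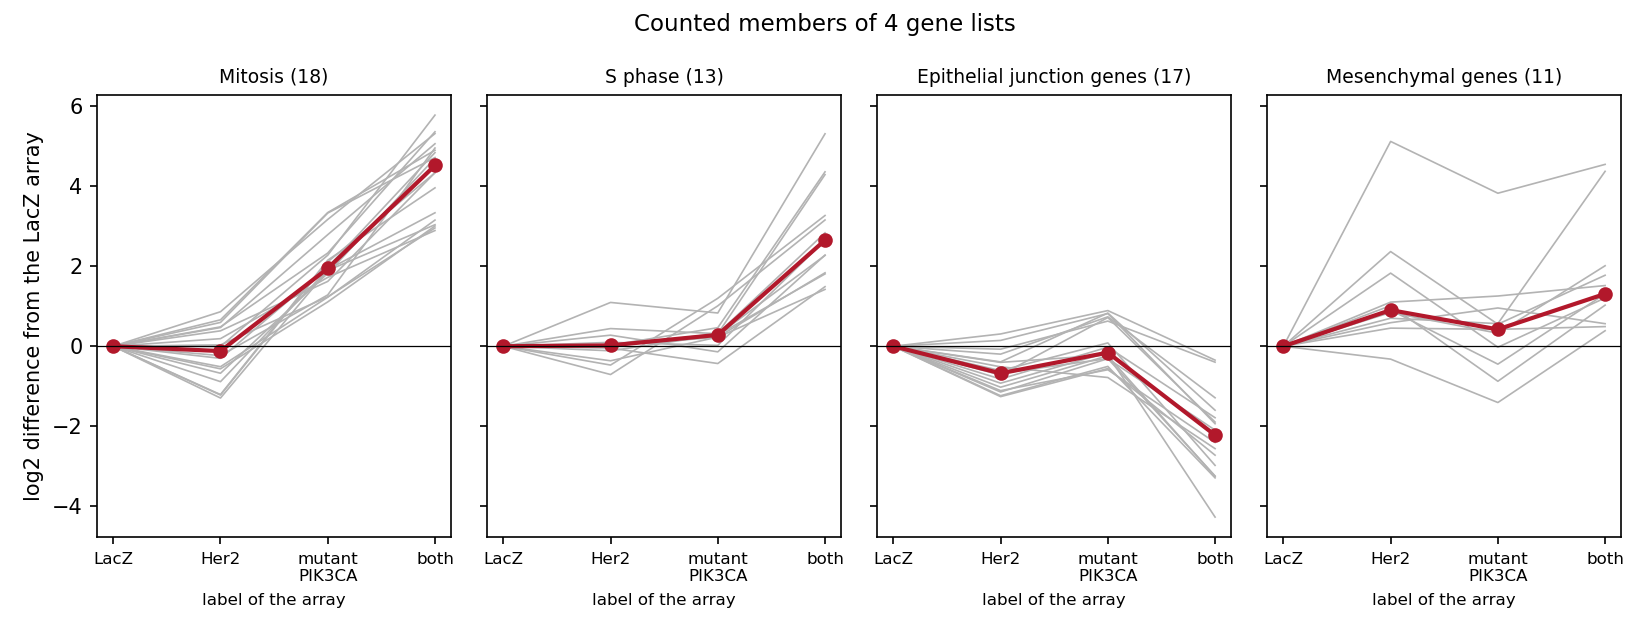
Log2 difference from the LacZ array (vertical axis) on the 4 arrays (horizontal axis, 1 array per group) for each counted gene of the mitosis (18), S phase (13), epithelial junction (17) and mesenchymal (11) lists, with a grey line per gene and the list median in red. The mitotic median is 1.95 on the array labelled mutant PIK3CA and 4.52 on the array labelled with both, and the junction median is -0.68 on the array labelled Her2 and -2.22 on the array labelled with both.

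The effects of both labels, each averaged over the backgrounds, were set against each other across genes. The averages of TYMS and ASPM were higher with each label and those of LSR, ADGRG1 and KLK6 lower, while ABCA6 and MMP2 were higher with the Her2 label and lower with the mutant PIK3CA label. Pearson's r was 0.461 and Spearman's rho 0.436 across genes, with 119 genes at least 2-fold higher for both averages, 43 lower for both and 16 opposite. Simulated arrays of equal noise gave an r of -0.0165 and a covariance of -0.0019, against an observed covariance of 0.197. By its construction this covariance is positive whenever the arrays labelled with both and LacZ stand farther apart than the single-gene arrays do, so it restates the distances between arrays and measures no shared effect. Without the filter on low values r was 0.325.

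An additive model fitted with limma over all 4 arrays called 0 genes for either term at an adjusted p under 0.05. Its smallest adjusted p was 0.513 for the Her2 term, shared by 314 genes, and 0.370 for the mutant PIK3CA term, shared by 39 genes, ABCA6 first among each. At an unadjusted p under 0.05 it gave 398 genes for Her2 (190 higher, 208 lower) and 505 for mutant PIK3CA (307 higher, 198 lower), where chance alone gives 216. With an intensity trend in the variance prior, limma called DPT for the Her2 term (log2 difference 4.57, adjusted p = 0.0085) and 0 genes for mutant PIK3CA. The residual of this model is the departure from additivity with 1 degree of freedom and not replicate error, and an exact permutation of 2 arrays against 2 cannot give a two-sided p below 0.333.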

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

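All tests in this part were chosen after the results were seen. The differences between backgrounds listed here were not tested, since each rests on 1 array per group. The TGF-beta target list moved oppositely with the Her2 label, at 0.46 without and -0.66 with mutant PIK3CA in the label (0.35 and -0.16 without the filter). Of the named genes, TOP2A went from -1.22 to 2.23 and H2BC14 from -1.65 to 4.59 between these backgrounds. In the other direction, CASP14 went from 1.88 to -1.60, CDH11 from 1.21 to -3.26, SCEL from 1.91 to -2.11, SLITRK6 from 2.22 to -2.36 and TIMP3 from 2.18 to -2.04. For the mutant PIK3CA label, without and with Her2, BMP6 gave 2.89 and -1.73, CALB2 1.34 and -1.94, SLITRK6 1.66 and -2.93, and H2BC14 -2.00 and 4.25. Among the probe sets unnamed here and outside every count, 1921 reached a log2 value of 5. Of these, 190 were at least 2-fold higher than on the LacZ array for the label Her2, 143 for mutant PIK3CA and 218 for both, and 126, 202 and 174 were at least 2-fold lower.

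The ERBB2 probe set read against the labels. Higher output of the whole region around ERBB2 is argued against by 4 of its neighbours (PGAP3 with a low signal), whose median difference on the array labelled mutant PIK3CA was -0.92. An exchange of the labels of the Her2 and mutant PIK3CA arrays remains a candidate explanation: the probe set was 4.19 higher on the array labelled mutant PIK3CA than on that labelled Her2, and both arrays that would then carry Her2 lay at least 1.43 above both that would not. A probe set that does not read the introduced copy stays open too, with a mean difference of -1.38 for the Her2 label, because no probe set used here tells the introduced from the resident gene, and no PIK3CA value was analysed here. If only the labels of the single-gene arrays were exchanged, every statement on such an array would change its gene, while both against LacZ would stand. Exchanges that involve the LacZ array or the array labelled with both were not examined. Under those, both against LacZ would not stand as given.

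Mitotic genes were higher with the mutant PIK3CA label. Normalization as the whole cause is argued against by a list median of 1.78 after cyclic loess, with 1.95 as deposited. The factor shared by the arrays labelled mutant PIK3CA and both stays open as a cause: 18 of 18 members were at least 2-fold higher in both pairs, but this restates the pattern, and the Her2 label also gave 18 of 18 in its second pair. The growth state of the cultures cannot be told apart from it either, with 1 culture per group: S phase genes had a median of 0.28 on the array labelled mutant PIK3CA (percentile 43.8 of random lists, 98.5 without the filter), and culture density is not given in the sources used here. Which introduced gene that factor would be depends on the labels weighed above.

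Epithelial genes were lower and mesenchymal genes higher on the array labelled with both. Admixed fibroblasts, weighed because LUM, DCN and DPT were high, stay open: COL1A1 and COL1A2, abundant in such cells, had a median difference of -0.24, and the 9 fibroblast markers measured without the filter one of -0.03 with 3 at least 2-fold higher, but COL1A1 and COL1A2 lie under the filter on every array, and abundant transcripts can read low here. Fewer epithelial cells stay open as well. The differences of 24 junction and basal genes had an SD of 1.35, against a spread of 0.479 for a difference of 2 arrays. Such unequal differences cannot decide it, because the level of these genes in any other cells was not measured. Normalization is argued against by a junction median of -2.26 after cyclic loess. A change within the cells carrying both genes, or in a subclone grown out during selection, may remain as a hypothesis, untested with 1 culture.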

How the results depend on the processing

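The exchange of labels and the filter at 3 were chosen after seeing the data. Of the counts and the correlation, 58 alternatives stayed within 1.5 times (for r, within 0.1) and 36 moved, the latter almost wholly through the number of genes or the threshold. Counts are given for Her2, mutant PIK3CA and both against LacZ, both against mutant PIK3CA and both against Her2, then Her2 and mutant PIK3CA the same way in both pairs, then additivity. With the filter at 7 they were 55, 130, 301, 243, 210, 28, 48 and 245. At 1.5-fold they were 961, 1387, 2062, 1642, 1471, 410, 515 and 1721. Without a filter, the counts that moved were 740, 951, 2286, 1831 and 1476, then 217 for Her2 the same way and 2127 for additivity, and with the filter at 3 they were 552, 808, 1979, 1546, 1226, 202 and 1542. More or fewer genes enter by construction. With the labels exchanged, Her2 against LacZ gave 481, mutant PIK3CA 239, and the same-way counts were 163 and 104. With an intensity trend the Her2 term of the limma fit called 1 gene, and the cause was not tested. The correlation between both effects was 0.325 without a filter. No total left the range of 1.5 times under quantile normalization, cyclic loess, the mean of probe sets or small RNAs kept, but under quantile normalization the same-way counts did by direction, with 33 higher for Her2 (main 52) and 71 higher and 76 lower for mutant PIK3CA (main 113 and 50). Of the list medians, 570 stayed within the array spread of 0.339, 37 moved, and of those outside the central 95% of random lists 1 turned, hypoxia targets in departure from additivity, at 0.00372 without a filter (main -0.68). Medians inside that range also changed sign without a filter, among them mesenchymal genes in departure from additivity at 0.51 (main -0.38) and PI3K components in both against LacZ at -0.14 (main 0.26), and the cause was not tested. Of the named genes' values under cyclic loess and the mean of probe sets, 189 stayed within that spread, 18 moved and 0 turned. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Differences from values near background, about the array medians of 1.13 to 1.17, are limited by signal.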

Other observations

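The tests on histones and on neighbouring genes were written before their results were seen, although the genes that prompted them had been, and the test on kallikreins counts as chosen after because KLK10 had been seen. Several lists had too few counted genes to be described. On the array labelled with both, the kallikreins of the squamous list were lower than on the LacZ array, KLK6 by -5.36, KLK7 by -3.25 and KLK10 by -2.64, and so was KLK5, at -3.41, which lies beside them. The squamous list as a whole was not lower there. Without the filter its 23 measured genes had a median of 0.15 (percentile 97.6), with 2 at least 2-fold higher and 4 lower. Secreted protease inhibitors of the antimicrobial list were lower there, SLPI at -2.45 and PI3 at -2.34, while the acute phase gene SAA1 was at 1.61 and complement C3 at -0.78. The only counted interferon-stimulated gene, IFI6, differed by 4.65, and without the filter 7 of 24 such genes were at least 2-fold higher, with a median of 0.40. Of the NRF2 targets, NQO1 differed by 2.37, ME1 by 1.12, TXNRD1 by 0.28 and SLC7A11 by -0.56. Of the inflammatory list, IL1A and TNFAIP3 were highest on the array labelled mutant PIK3CA, at 2.40 and 3.06 above LacZ, and NFKBIA differed by -0.16, and without the filter 6 of 25 genes of this list were at least 2-fold higher there. There OXTR, of the myoepithelial list, stood at 1.90, and MME at 0.26. The leukocyte-list genes CD68 and LAPTM5, both also expressed outside leukocytes, differed by 2.10 and 3.08 on the array labelled with both. The fibroblast gene FAP differed by 0.52 there, and no endothelial marker was counted.

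H2BC14 and H1-5 lay farthest above additivity. The other 26 replication-dependent histone genes, measured without a filter, had a median difference of 0.26 for both against LacZ, at percentile 99.8 of random lists. This leaves room for a small shift of the group on the array labelled with both. There 4 genes were at least 2-fold higher than on the LacZ array (H1-1, H1-2, H2AC21 and H3C13) and 0 lower. H3C13 was higher on the single-gene arrays too (LacZ 1.41, Her2 2.34, mutant PIK3CA 2.27, both 2.73), with a departure from additivity of -0.47. Most of the 26 genes read under a log2 value of 3 on every array, so their median rests largely on low signals. Their median departure was 0.30. Histone genes resemble each other, and probe sets may read more than 1 of them.

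Genes lower with the mutant PIK3CA label lay partly side by side. The lowest median of 10 neighbouring counted genes was -1.02, on chromosome 17 from PRKAR1A to SLC38A12 and including ABCA6 and SOX9, and 0 of 1000 shuffled gene orders gave one as low. The median of this run was -1.22 on the array labelled mutant PIK3CA against LacZ and -0.74 for both against Her2. It was also lower with the Her2 label, at -0.43 for Her2 against LacZ and -0.42 for both against mutant PIK3CA. A copy number difference between the cultures may be a candidate explanation, but the test does not single it out: the highest and lowest run of each of the 5 comparisons searched lay beyond at least 95% of shuffled orders. Among them were PVR to VASP on chromosome 19 for Her2 against LacZ (-0.90, share 0.003), ODR4 to KIF14 on chromosome 1 for the mutant PIK3CA label (1.19, share 0.013) and RRAS to KLK10 on chromosome 19 for both against LacZ (-1.60, share 0), which holds kallikreins. Neighbouring genes that are regulated together would give such runs too, and copy number was not analysed here.

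Kallikrein genes other than KLK5, KLK6 and KLK7 were tested for a shift of the group. The 2 that reached a log2 value of 3, KLK9 and KLK10, had a median difference of -2.01 for both against LacZ, which is consistent with one, but 2 genes are few, and KLK10 was known to be lower when the test was written.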
